A study of Aspergillus nidulans with 16 samples.

How the data were processed

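Aspergillus nidulans mycelium was grown at 30 °C for 15 h with shaking at 150 rpm in 400 mL of minimal medium, with fructose (0.1%) as carbon source and urea (5 mM) as nitrogen source, per the labels' protocols. RNA was extracted with guanidine and purified again with Trizol, and 200 ng of total RNA was labelled, with Cy3 for the culture and Cy5 for the reference pool, per the labels. No dyes were swapped. The design text states that the 8 cultures of each strain were grown and harvested separately in 2 culture batches, 4 cultures of each strain in each, with 1 array per culture and no repeated hybridisation. Which cultures formed a batch is open, because the batch numbers stand in the description field, which disagrees with the titles on the strain of 8 arrays. That field gives batch 1 for all 8 arrays titled CV125 and batch 2 for all 8 titled NA1363, against the design text. Joined to the titles' strains, these batch numbers would leave batch and strain inseparable. Read with its own strain names, the field puts 4 cultures of each strain in each batch, as the design text does. Replicates 1 to 4 and 5 to 8 of the titles were presumed to be the batches, and values by batch rest on that presumption.

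The deposited scanner files hold, per the file headers, mean foreground and median local background intensity of each spot in both channels, extracted with Agilent Feature Extraction 10.7.3.1 (protocol GE2_107_Sep09) and neither background-subtracted nor dye-normalised in those columns. They also hold processed intensity values that Feature Extraction subtracted for background and normalised between dyes, per the file headers, and their log10 ratio of Cy5 over Cy3. The authors' deposited table of the series holds log2 values of Cy3 over Cy5. That scale and direction were found from the values: against the log10 ratio of the scanner files turned to log2, each column had a slope of -1.00288 to -0.998192 and a correlation across probes of -0.999 to -0.939. Column medians lay between -0.011 and 0.0361, and whether the authors centred them, or how they summarised spots, is not given in the sources used here. The direction of every difference below is NA1363 minus CV125, from the dyes named in the labels.

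Each array held 15744 spots, of which 536 were control spots. The 15208 gene spots stood for 15124 probes of 10551 genes, 5991 genes with 1 probe, 4548 with 2 and 12 with more, and 21 probes were spotted 5 times. Between 3 and 52 spots per array were marked as non-uniform or as outliers by Feature Extraction and left out, and no spot was saturated (0 on every array). The intensity was background-corrected with normexp (offset 50) on foreground and background signals, and log2 ratios were normalised within each array by loess with control spots at weight 0. The offset draws the ratios of dim probes towards 0, so large fold changes against a dim strain are understated. Spots of a probe were averaged, and probes were kept where Cy3 was well above background on at least 8 of the 16 arrays (13145 probes). The kept probes of a gene were averaged, which left 8998 genes, 41 of them with a missing value on some array. Of 4135 genes with at least 2 kept probes, 1 had probes called in opposite directions. Probes of a gene can overlap or repeat, as those of riboB and gpdA do, so they are not always separate readings. Of the 2613 genes called, 151 were below the limit for background on at least 1 of the 16 arrays; stcQ, which is named, was above it on 7 of 8 NA1363 arrays. A single called gene, not named, was above it on none of the CV125 arrays, and 0 called genes on none of the NA1363 arrays.

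Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 ratios, strain as the only term, all 16 arrays, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Replicate numbers, slides and presumed batches entered as blocks only in alternatives. The test was tried on data simulated for the same comparison over the 8957 genes without missing values: it called 26% of genes changed by 0.25 in log2, 86% of those changed by 0.5 and 100% of those changed by 1 or 2, and 4 of 8757 unchanged genes. The test of a slope by slide order, simulated over the same genes, found 46.5% of 200 genes whose strain difference changed by 0.3 per slide, and 9 others. Noise in both simulations was drawn independently for each gene and array, with the same SD in both strains. The data hold deviations shared between arrays and unequal SDs, so these rates of false calls need not hold for them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

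Gene lists were fixed before the data were examined: 17 lists of locus numbers written from knowledge of the field and 18 lists of words sought in the product descriptions of the files. Of the written list members 23 were dropped because the reference table gave the locus another symbol and 1 was not on the array, from 170. Lists with at least 3 measured members were tested with limma's camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the 30 lists tested, and again with an estimated correlation. The camera p values given for the lists test a list against all other genes. Limma's fry, planned beside it, asks only whether the genes of a list differ between the strains. Genes were named by a rule also fixed before the data were examined: the elements of the construct and pabA, the 12 called genes with the highest and the 12 with the lowest log2 fold change, up to 4 called members of each list by size (or 1 to 2 members of lowest p where none was called), and up to 4 genes of each of the 3 longest runs of neighbours called in one direction. Of these, genes whose call rested on single arrays are mostly left out of the report. The genes alcA and AN0644, the members of the sterol list that no part of the rule takes, and the tests of slide order were chosen after the values were seen.

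Locus identifiers and descriptions are those of the array files. Symbols and the order of genes along chromosomes came from the RefSeq gene table of assembly ASM1142v1, in which 8359 of the 8998 genes tested matched and 639 did not; 776 genes of the array had a symbol there. The genome build behind the array design is not given in the sources used here, so no coordinates are printed. Changed genes per chromosome were compared with Fisher's exact test, and adjacency with a permutation of the calls along the gene order in 100000 resamples.

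Alternatives covered the background correction, the normalisation within and between arrays, the Cy3 channel without its reference, the processed intensity and the deposited log2 table, the filter on dim probes, the summary of probes, blocks for replicate number, slide and presumed batch, fits within each batch and slide, array weights, the groups as the description field names them, each array left out in turn, and other thresholds. Fits on slides 1 and 2, on slides 3 and 4, on all slides without genes that moved with slide order, and of the riboflavin list without riboB were added after the data had been seen.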

Results

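Transcript levels were measured in mycelium of the filamentous fungus Aspergillus nidulans for a control strain, CV125, which carries the pabaA1 marker, and a transgenic strain, NA1363. Per the labels, NA1363 carries a construct on chromosome VIII in which the promoter of gpdA drives Escherichia coli lacZ, the gene for beta-galactosidase, followed by the trpC terminator and riboB. Each strain was represented by 8 cultures with 1 array per culture, and RNA of the culture (Cy3) was hybridised beside a reference pool (Cy5) made from CV125, NA1363 and the related transgenic strains NA1360 and NA1359. The median Cy3 signal per array ran from 373 to 684 against a median local background of 24 to 34, and 12211 to 14043 of the 15124 gene probes were well above background in Cy3. The number of arrays limits the precision of every value below. The arrays lay on 4 slides, each holding 2 arrays of either strain. The median Cy5 signal per array ran from 158 to 472 and was lowest on slide 4 in both strains, at 158 to 224.

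The label field with the sample description names the other strain for CV125 replicates 5 to 8 and NA1363 replicates 1 to 4, so groups were taken from the sample titles, which the source and strain fields match. The batch number in that field is 1 on every array titled CV125 and 2 on every array titled NA1363. If it held for each array, batch and strain could not be separated. The design text, however, puts 4 cultures of each strain in each batch, and so does that field when read with its own strain names. The lacZ ratio put 0 of 16 arrays with the other strain: the lowest NA1363 array stood at 0.62 and the highest CV125 array at -3.08 (log2 of Cy3 over Cy5). Correlations of arrays across genes were 0.293 to 0.882 within a strain and -0.266 to 0.169 between strains. The genes are not independent replicates in these correlations.

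The first comparison asked whether the parts of the construct were seen in the strain labelled as carrying it. The probes for lacZ, trpC and riboB all read higher in NA1363. The only trpC probe cannot tell the native transcript from a trpC stretch that the construct may carry. The gene gpdA, which encodes the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase, did not differ past the threshold. The lacZ ratio was 0.78 ± 0.15 (SD, n = 8) in NA1363 and -3.43 ± 0.21 in CV125, a log2 difference of at least 4.21 (SE 0.09, limma adjusted p = 4.14e-17). This mean of 2 probes is a lower limit and no fold is given, since 1 of them was above background on only 2 of 8 CV125 arrays. The probe for trpC (AN0648), a tryptophan synthesis gene on chromosome VIII, gave the largest measured difference of all genes tested, with lacZ known only as a lower limit. The trpC ratio was 0.73 ± 0.13 in NA1363 against -5.11 ± 0.12 in CV125, 57.3-fold, with a log2 difference of 5.84 (SE 0.07, limma adjusted p = 2.5e-21). The riboflavin synthesis gene riboB (AN0670), for GTP cyclohydrolase II, was 2.67-fold higher (log2 difference 1.42, SE 0.06, limma adjusted p = 2e-12).

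On all 8 NA1363 arrays, lacZ, trpC and riboB stood above every CV125 array. The lacZ difference was 5.17 with the probe above background on 8 of 8 CV125 arrays and at least 3.25 with the other. Only 1 probe stood for trpC, whereas the 4 riboB probes gave differences of 1.33 to 1.5. The riboB probes overlap almost wholly in pairs, so they are not 4 separate readings, and the gpdA probes share the same sequence. The gpdA difference was -0.05 (SE 0.07, limma adjusted p = 0.598). The gene pabA (AN6550), for p-aminobenzoate synthase and mutated in both strains per their labels, was higher in NA1363 by 0.45 (SE 0.07, limma adjusted p = 9.07e-05), with 6 of 8 NA1363 arrays above every CV125 array. Fitted with slide as a block, the adjusted p was 1.44e-14 for lacZ, 1.66e-18 for trpC, 6.51e-11 for riboB and 2e-04 for pabA. Within slides 1 to 4 the lacZ difference was at least 4.25, 4.57, 4.18 and 3.84, again as lower limits. That of trpC was 5.85, 5.92, 5.94 and 5.65, and that of riboB 1.28, 1.44, 1.44 and 1.51. The pabA difference was not past the threshold with the arrays of slides 3 and 4 alone, at 0.41.

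**Figure D1:**
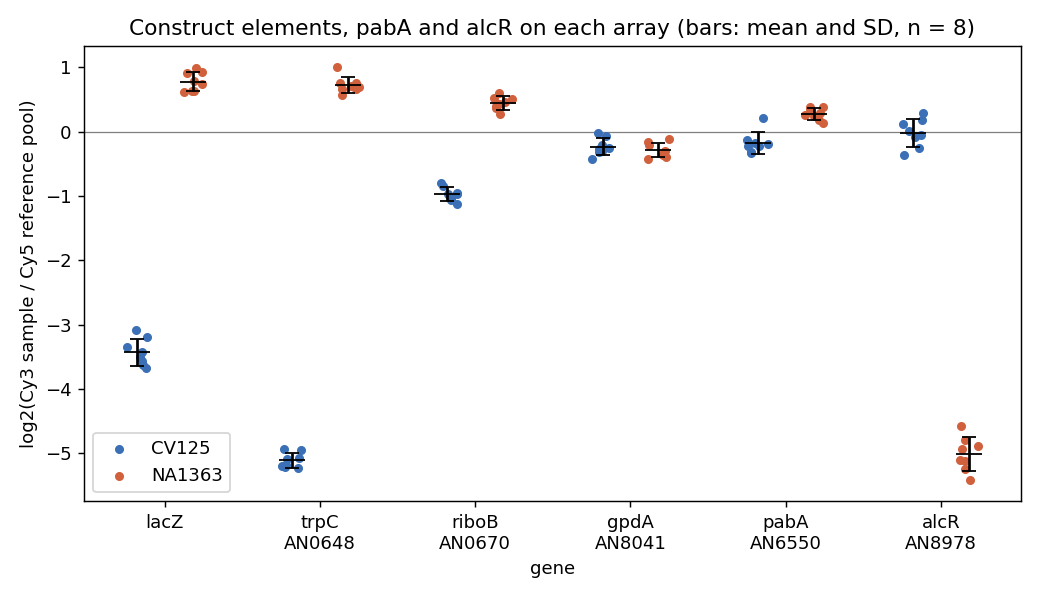
Log2 ratio of the Cy3 sample over the Cy5 reference pool on each of the 16 arrays for lacZ, trpC, riboB, gpdA, pabA and alcR, with CV125 in blue, NA1363 in orange, and bars for the mean and SD of 8 arrays. The strains do not overlap for lacZ, trpC, riboB and alcR, with lacZ at 0.78 in NA1363 and -3.43 in CV125.

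Across the genome, the larger changes were nearly all increases in NA1363. Of 8998 genes tested, 2613 (29.0%) differed at a limma adjusted p under 0.05, 1361 higher and 1252 lower in NA1363, and the median size of these differences was 0.36 in log2. Among them 195 differed at least 2-fold, 184 higher and 11 lower. With the processed signals 368 differed at least 2-fold (316 higher, 52 lower) and with the deposited log2 ratios 367. In both, more changed genes were lower than higher (1306 higher and 1568 lower, and 1303 and 1566). The median log2 difference over all genes was -0.0002, and the median SD between arrays of one strain was 0.17. The largest decrease was that of alcR (AN8978), the activator of the ethanol utilisation genes, at a log2 difference of -5.00 (SE 0.11, limma adjusted p = 1.42e-16).

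Behind trpC, and with lacZ left aside as a lower limit, the highest increases were those of AN1549 and AN9297. The log2 difference was 5.64 (SE 0.11) for AN1549, a conserved hypothetical protein, and 5.62 (SE 0.16) for AN9297, of the myosin-cross-reactive antigen family. They were followed by the conserved hypothetical protein AN4127 (5.25, SE 0.14), the C-4 methylsterol oxidase AN8907 (5.00, SE 0.17), an enzyme class of sterol synthesis, and frdA (AN10296), an FAD dependent oxidoreductase (4.61, SE 0.13). The stearoyl-CoA desaturase AN4135, which makes unsaturated fatty acids, rose by 4.39 (SE 0.10), the alternative oxidase AN2099, which passes electrons to oxygen outside the cytochrome pathway, by 4.04 (SE 0.59), and the monosaccharide transporter AN5860 by 3.92 (SE 0.14). The hypothetical proteins AN2798 (4.54, SE 0.09) and AN4051 (4.32, SE 0.19) belonged to the same 12 genes. Their limma adjusted p ran up to 4.48e-05, for AN2099, and on all 8 NA1363 arrays each stood above every CV125 array.

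The other genes among the 12 lowest fell by less than alcR. Of these, 2 are not described here because leaving out single arrays ended their calls. In alcR all 8 NA1363 arrays lay below every CV125 array, with means of -5.01 ± 0.27 in NA1363 and -0.02 ± 0.22 in CV125 (SD, n = 8). Its chromosomal neighbour alcA (AN8979), for alcohol dehydrogenase I, was lower by a log2 difference of -0.33 (SE 0.06, limma adjusted p = 0.000375). The PhiA protein gene AN8333 (aspf34) fell by 1.43 (SE 0.22, limma adjusted p = 7.06e-05), the Sec61beta subunit AN0417 of the translocon, which carries proteins into the endoplasmic reticulum, fell by 1.35 (SE 0.16, adjusted p = 6.1e-06; -2.07, -1.50, -1.09 and -0.72 on slides 1 to 4), and the ZIP metal ion transporter AN6216 fell by 1.11 (SE 0.09, adjusted p = 6.56e-08). The differences were -1.26 (SE 0.20) for the O-methyl transferase B gene AN12090, -1.13 (SE 0.13) for AN7812, of the sterigmatocystin cluster, -1.06 (SE 0.14) for the surface protein 1 gene AN0493, and -1.05 and -1.0 for the hypothetical proteins AN9001 and AN7087. The hypothetical protein AN11584 fell by 1.95 (SE 0.50, adjusted p = 0.00609), with 4 of 8 NA1363 arrays below every CV125 array and SDs of 0.91 and 1.30. Its differences within the presumed batches were -1.60 and -2.31.

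**Figure D2:**
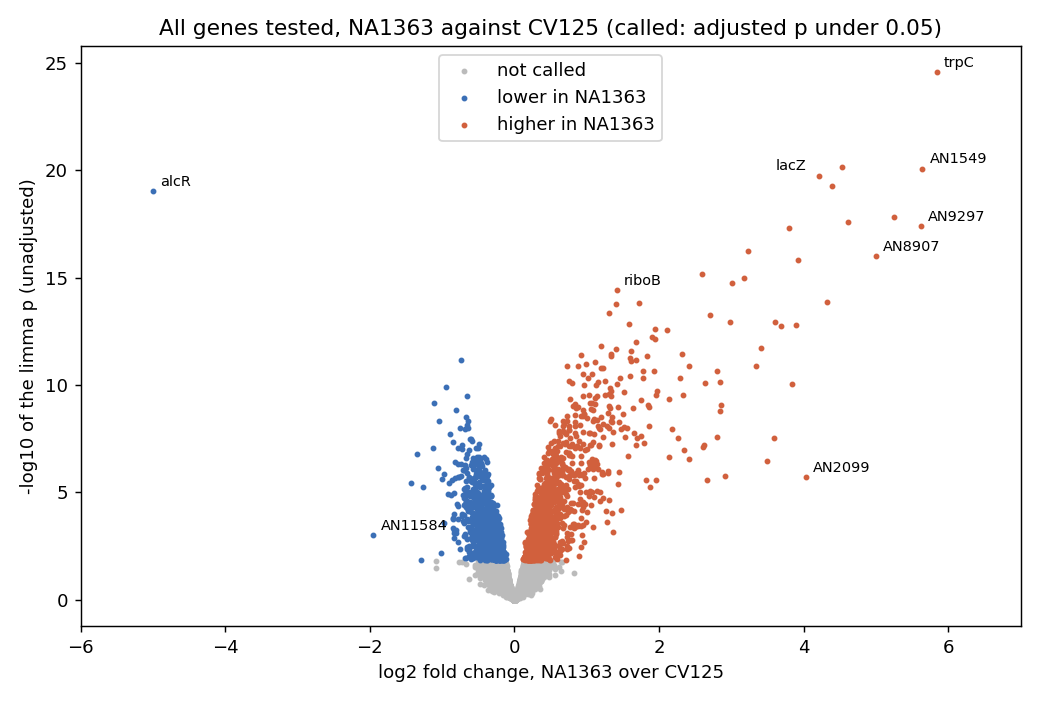
Log2 fold change of NA1363 over CV125 (x) against -log10 of the unadjusted limma p (y) for the 8998 genes tested, with 1361 genes higher in orange, 1252 lower in blue and the others in grey. Increases reach 5.84 for trpC, and alcR at -5.00 stands alone among the decreases.

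With slide as a block, 2596 changed genes were called (1369 higher, 1227 lower), and with 2 arrays of each strain within slides 1, 2, 3 and 4 the counts were 601, 456, 150 and 35. With the presumed culture batch (replicates 1 to 4 and 5 to 8) as a block, 3004 genes were called, and within these batches 1684 and 1517. Levels of 304 genes moved with slide order within CV125 at a limma adjusted p under 0.05, 223 of them rising, against 0 genes within NA1363 (430 at an unadjusted p under 0.05, against 1767 in CV125). The strain difference itself changed with slide order for 60 genes. Of the 184 genes at least 2-fold higher in NA1363, 60 were among the 304, and the median strain difference of the 184 was 1.67, 1.60, 1.44 and 1.23 on slides 1 to 4. Without the 304 genes, 2440 genes were called and 133 of them differed at least 2-fold.

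**Figure D3:**
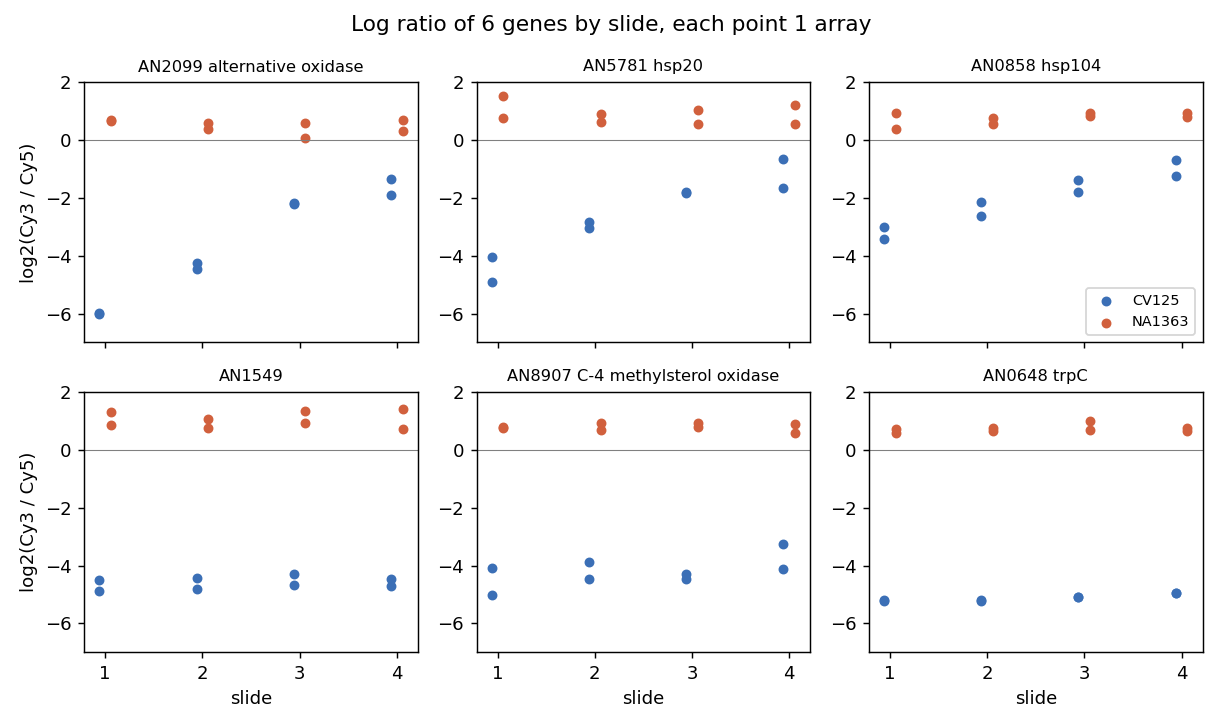
Log2 ratio of Cy3 over Cy5 (y) by slide (x) for 6 genes, each point 1 array, with CV125 in blue and NA1363 in orange. The strain difference falls from 6.67 to 2.13 from slide 1 to slide 4 for AN2099 and from 5.62 to 2.06 for hsp20, and stays between 5.53 and 5.75 for AN1549.

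Gene groups fixed before the data were examined were tested next, to describe which functions moved together. Camera called the heat shock list as higher in NA1363 than other genes, and those of cytosolic ribosomal proteins, of the sterigmatocystin cluster and, with more members not called than lower, of the respiratory chain as lower. Of 30 lists with at least 3 measured members, 6 were called by limma's camera, and the other 24 were not. With a correlation between genes estimated from the data in place of the preset 0.01, only the host genes of the construct remained called (adjusted p = 0.0251, against 0.000281). That list holds riboB and trpC, whose probes both read higher, and gpdA, and was chosen because the construct carries their parts. The estimated correlation was 0.57 for heat shock, 0.51 for the sterigmatocystin cluster and 0.27 for cytosolic ribosomal proteins. By fry, which does not compare a list with other genes, all 6 lists passed (largest adjusted p = 0.008, respiratory chain). So did lists that camera did not call, such as glycolysis (fry adjusted p = 0.000164), though not translation factors (0.564).

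Of the 4 heat shock genes, 3 rose and 1 was not called (mean log2 difference 1.88, camera adjusted p = 0.00375; adjusted p = 0.326 with an estimated correlation). The small heat shock protein hsp20 (AN5781) rose by 3.50 (SE 0.45), the disaggregase hsp104 (AN0858) by 2.80 (SE 0.30) and hsp70 (AN5129) by 0.91 (SE 0.15), with the largest limma adjusted p at 0.000163. All 3 moved with slide order in CV125: the mean slope of the list was 0.59 per slide in CV125 and 0.08 in NA1363, and its mean strain difference was 2.75, 2.02, 1.59 and 1.18 on slides 1 to 4. Within the presumed batches this mean was 1.98 and 1.79, and with slide as a block the camera adjusted p was 0.00085. Of 31 chaperones 9 rose and 2 fell (11 and 4 adjusted over the list alone), among them the mitochondrial hsp78 (AN1163) at 2.85 (SE 0.25; 3.69 on slide 1, 2.18 on slide 4) and the heat shock protein AN3555 at 2.91 (SE 0.42; 4.64 on slide 1, 2.04 on slide 4). Camera did not call that list (adjusted p = 0.0512), though it did with slide as a block (adjusted p = 0.0427), and 6 of its members moved with slide order in CV125.

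Genes for cytosolic ribosomal proteins were lower by a small, widely shared amount: 36 of 70 fell and 1 rose (41 and 1 adjusted over the list alone), with a mean log2 difference of -0.27 (camera adjusted p = 8.71e-08; adjusted p = 0.326 with an estimated correlation). AN4222, for 60S protein L27-A, fell by 0.71 (SE 0.15), AN6679, for a 40S protein, by 0.69 (SE 0.10) and AN0907, for 40S protein S22, by 0.65 (SE 0.14). The list mean was -0.42, -0.28, -0.26 and -0.12 on slides 1 to 4, with a mean slope of -0.09 per slide in CV125 and 0.00235 in NA1363, and -0.21 and -0.33 in the presumed batches (slide as a block, adjusted p = 8.84e-08). Of the 70 respiratory chain genes 26 fell and 9 rose (28 and 10 adjusted over the list alone; mean -0.09, camera adjusted p = 0.0376; adjusted p = 0.426 with an estimated correlation). Among single members, AN6630 (ATP synthase subunit D) fell by 0.61 (SE 0.10), AN10032 (ATP synthase subunit delta) fell by 0.57 (SE 0.07) and AN4300, of NADH-ubiquinone oxidoreductase, fell by 0.58 (SE 0.11), whereas AN7500, of the same complex, rose by 0.83 (SE 0.19; 1.48, 0.85, 0.78 and 0.21 on slides 1 to 4). In CV125, 5 of the 70 genes moved with slide order, AN7500 among them, and the mean slope was -0.05. Slide means of that list were -0.18, -0.07, -0.07 and -0.04, batch means -0.07 and -0.11, and the adjusted p 0.0345 with slide as a block. Its call was lost without CV125 replicate 1 (adjusted p = 0.0655) or 5 (0.053), and with median centring (0.0723).

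In the cluster for sterigmatocystin, a polyketide mycotoxin, 15 of 19 measured genes fell and 0 rose (16 and 0 adjusted over the list alone), with a mean of -0.47 (camera adjusted p = 2.72e-07; adjusted p = 0.326 with an estimated correlation). The ketoreductase gene stcE (AN7821) fell by 0.87 (SE 0.15), AN7809 by 0.83 (SE 0.14) and the polyketide synthase AN7825 by 0.77 (SE 0.16), with limma adjusted p up to 0.0016. The list mean was -0.46, -0.63, -0.46 and -0.34 on slides 1 to 4 and -0.34 and -0.60 in the presumed batches (slide as a block, adjusted p = 9.54e-07). Other secondary metabolite genes did not move as a list (1 of 18 rose and 1 fell; 1 and 0 adjusted over the list alone; camera adjusted p = 0.497), and of 17 polyketide and peptide synthases 2 rose and 3 fell (2 and 4 adjusted over the list alone, 0.403). The 2 measured penicillin genes, ipnA (0.15, SE 0.07) and aatA (0.03, SE 0.09), were not called.

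Of 8 riboflavin and flavin genes 4 rose (6 adjusted over the list alone; mean 0.30, camera adjusted p = 0.0337; adjusted p = 0.187 with an estimated correlation). Besides the construct's own riboB these were the riboflavin-specific deaminase AN6979 (0.26, SE 0.07), fmn1 (AN7469, riboflavin kinase; 0.24, SE 0.07) and AN11968, for Rib7 (0.16, SE 0.05). The list mean was 0.24, 0.30, 0.31 and 0.33 on slides 1 to 4 and 0.30 and 0.29 in the presumed batches, with an adjusted p of 0.041 with slide as a block. The call was lost with median centring, at 0.0544, and with the replicate number as a block. It rested on riboB, since the other 7 genes had a mean of 0.14 and a camera adjusted p of 0.212. The host gene list had means of 2.38, 2.41, 2.47 and 2.34 on the slides and 2.41 and 2.39 in the batches (slide as a block, adjusted p = 0.000696).

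**Figure D4:**
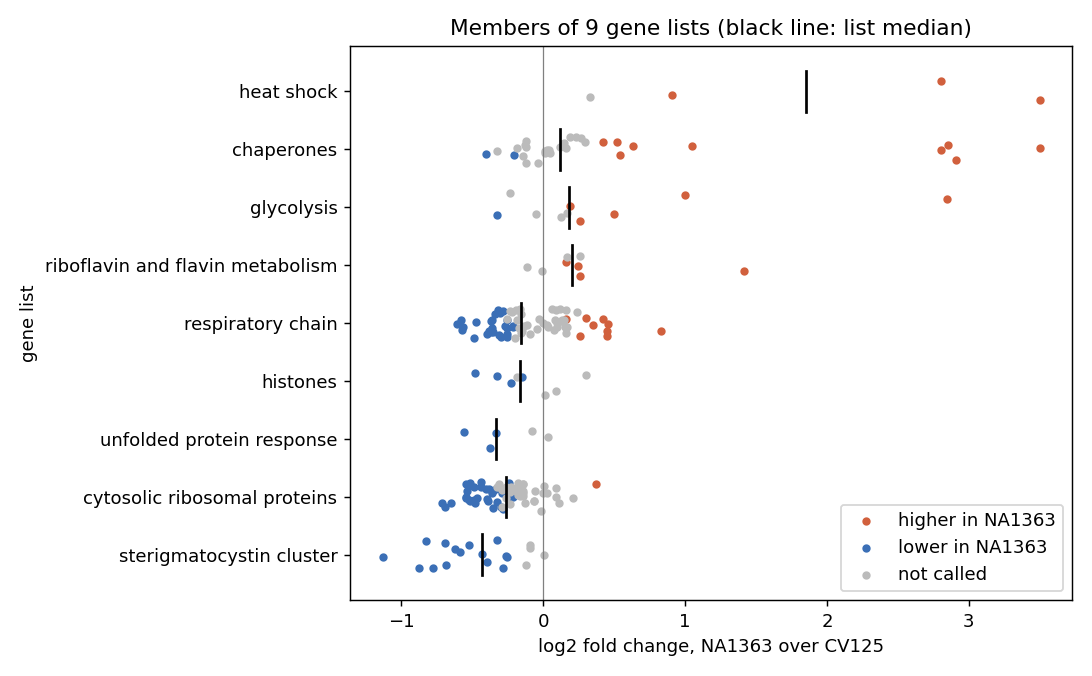
Log2 fold change of NA1363 over CV125 (x) for every measured member of 9 gene lists (y), with called members in orange (higher) or blue (lower), the others in grey and a black line at the list median. Of the 70 cytosolic ribosomal protein genes 36 are lower, and of the 4 heat shock genes 3 are higher.

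Primary metabolism held single large changes in lists that camera did not call. Of 10 glycolysis genes 5 rose and 1 fell (camera adjusted p = 0.0512): pdcA (AN4888), for pyruvate decarboxylase at the start of ethanol fermentation, rose by 2.85 (SE 0.21), pfkA (AN3223), for phosphofructokinase, by 1.00 (SE 0.09) and glkA (AN8689), for glucokinase, by 0.50 (SE 0.10; 0.86, 0.65, 0.37 and 0.12 on slides 1 to 4), and tpiA (AN6900) fell by 0.33 (SE 0.09). Among 9 genes of alternative carbon use 4 rose and 2 fell (0.940). The glyoxylate cycle genes acuE (AN6653, malate synthase) and acuD (AN5634, isocitrate lyase) rose by 1.29 (SE 0.18) and 1.18 (SE 0.19), with 1.47 and 1.49 on slide 1 and 0.78 and 0.70 on slide 4. In CV125, 4 of the 9 moved with slide order. Here alcR and alcA were the ones that fell. Of 18 genes of nitrogen metabolism 7 rose and 3 fell (7 and 5 adjusted over the list alone, 0.497). The uricase gene uaZ (AN9470) rose by 1.30 (SE 0.18) and niiA (AN1007), for nitrite reductase, by 1.13 (SE 0.09), while the proline permease prnB (AN1732) fell by 0.65 (SE 0.12). The uaZ difference was 2.04, 1.63, 0.96 and 0.57 on slides 1 to 4.

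In the secretory pathway, 3 of 5 genes of the unfolded protein response fell (camera adjusted p = 0.0512), namely calnexin (clxA, AN3592) by 0.56 (SE 0.10) and the disulfide isomerases tigA (AN0075) by 0.38 (SE 0.05) and pdiA (AN7436) by 0.33 (SE 0.09). Of 8 histone genes 4 fell (5 adjusted over the list alone, 0.125), the H4 genes AN0734 and AN2426 by 0.48 (SE 0.08) and 0.33 (SE 0.06). Among 23 amino acid transporters 2 rose and 7 fell (3 and 9 adjusted over the list alone, 0.0979), with AN7150 up by 0.79 (SE 0.10) and AN0010 down, at -0.67 (SE 0.11). Of 17 genes of asexual development 4 rose (0.576), led by conJ (AN5015) at 0.73 (SE 0.22), and of 7 of sexual development 2 fell (0.212), steA (AN2290) by 0.61 (SE 0.13) and nsdD (AN3152) by 0.25 (SE 0.06).

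The wider families went both ways, and camera called none of them. Major facilitator transporters had 24 of 148 higher and 21 lower (24 and 23 adjusted over the list alone; camera adjusted p = 0.940), with the multidrug transporter AN7295 at 2.61 (SE 0.30; 3.72 on slide 1, 1.26 on slide 4), and sugar transporters 9 of 52 higher and 7 lower (9 and 8 adjusted over the list alone, 0.646), with AN2585 at 2.14 (SE 0.18; 2.30 on slide 1, 1.47 on slide 4). Glycoside hydrolases, a list that includes lacZ, had 12 of 83 higher and 10 lower (0.646), with the endoglucanase AN8068 at 1.41 (SE 0.06). The galactose and lactose list, which also includes lacZ, had 3 of 17 higher and 3 lower (0.680), cytochromes P450 5 of 35 higher and 5 lower (0.995), with the sterol 14 alpha-demethylase AN1901 at 1.91 (SE 0.11), and translation factors 5 of 34 higher and 5 lower (0.646), with the elongation factor subunit AN9304 at 1.35 (SE 0.13). Proteasome genes had 5 of 34 higher and 2 lower (0.254), DNA repair genes 1 of 32 higher and 3 lower (0.434), and mitochondrial ribosomal proteins 1 of 7 higher and 2 lower (0.576).

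In the smallest lists, 1 of 3 oxidative stress genes rose, the thioredoxin trxA (AN0170) by 0.78 (SE 0.11, list 0.497), 1 of 7 plant polysaccharide genes rose, cbhB (AN0494) by 0.27 (SE 0.06, list 0.510), 1 of 3 starch genes fell, the regulator amyR (AN2016) by 0.37 (SE 0.07, list 0.680), and 1 of 6 iron genes fell (0 adjusted over the list alone, list 0.940). Lists with fewer than 3 measured members were not tested as lists: neither the cell wall genes fksA and csmB nor the beta-tubulin genes benA (-0.08, SE 0.08) and tubC (-0.02, SE 0.06) were called, 1 of 2 heterokaryon incompatibility genes was lower, and the keyword for transposable elements matched only a telomerase reverse transcriptase gene, AN3753 (-0.05, SE 0.05). For each list not given a second count here, the counts were the same adjusted over the list alone. The mean and the median differed in sign for cytochromes P450, major facilitator and sugar transporters, translation factors, iron and starch genes.

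The position of changed genes was compared last, since the construct of NA1363 lies on chromosome VIII. Changed genes did not gather there: 428 of 1418 tested genes of chromosome VIII (30.2%) differed, an odds ratio of 1.07 against the other chromosomes (Fisher's exact test, two-sided, adjusted p = 0.556 over 8 chromosomes). No chromosome passed the threshold, the nearest being chromosome IV with 251 of 753 genes (odds ratio 1.25, adjusted p = 0.064), which passed when genes were chosen at an unadjusted p under 0.01 (odds ratio 1.26, adjusted p = 0.0458). Changed genes did lie next to each other more often than a random placing gave: 458 changed genes had a next neighbour changed the same way, against a mean of 353 (SD 16.3) and a maximum of 419 in 100000 resamples (permutation test, one-sided, p = 1e-05, the smallest they can give).

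Runs of at least 3 neighbours changed in one direction numbered 77, of which 49 were higher and 28 lower. The longest held 7 genes on chromosome VI, all lower, among them the GNAT family acetyltransferase AN3344 (-0.50, SE 0.13) and the GABA permease AN3347 (-0.44, SE 0.10). The next, of 6 genes on chromosome IV, ran through the sterigmatocystin cluster with the versicolorin reductase AN7806 (-0.68, SE 0.18), stcW (AN7804; -0.62, SE 0.14) and stcQ (AN7810; -0.43, SE 0.09). A run of 5 lower genes on chromosome II included the Yip1 family member AN4017 (-0.51, SE 0.11) and AN4016, of the ubiquitin family (-0.38, SE 0.12).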

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

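The tests of slide order and of the reasons weighed here were chosen after the result had been seen; the counts over other splits of the arrays were planned before. In 100 splits of the 16 arrays into 8 and 8, the real one included, only the real split (1) gave as many changed genes as 2613 (highest other 425) and only it (1) gave 195 genes changed at least 2-fold (highest other 76). As many called lists as 6 came from 3 of the splits, the highest other calling 7. All 3 shares lay under 0.05, the limit set for chance. At least 1 list was called in 68 of the 99 other splits, but many of these divided the strains unevenly and so were not free of a strain difference. The other splits with 6 and 7 lists had 2 and 6 NA1363 arrays in their first group. A split with 4 NA1363 arrays in each group still called 5 lists, so list calls can arise without a strain difference. The split with 425 genes put 7 NA1363 arrays into one group. A split along the presumed batches called 580 genes and 4 lists, and one of slides 3 and 4 against slides 1 and 2 called 0 genes with limma but also 4 lists.

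In 19 of 260 groups of 8 arrays that were looked at, 1 array stood far from the others; chance does this in about 1 in 20 groups, or 13 of them. NA1363 replicate 3 stood apart for trpC (AN0648) at 1.01, ureA (AN0418) at -1.36, trxA (AN0170) at 0.80 and AN2585 at 1.28. NA1363 replicate 5 stood apart for AN4492 at 0.55, AN4457 at -0.45, AN7150 at -0.44 and AN7915 at -0.149, NA1363 replicate 4 for steA (AN2290) at -1.19, htz1 (AN8039) at -0.61 and AN0044 at -0.54, and NA1363 replicate 1 for AN0116 at -0.117. CV125 replicate 8 stood apart for pabA (AN6550) at 0.217, flbB (AN7542) at -0.60, pfkA (AN3223) at 0.0729, cbhB (AN0494) at -0.43 and AN1080 at -0.20, CV125 replicate 1 for clxA (AN3592) at 0.42 and CV125 replicate 4 for AN4017 at 0.70. The call of htz1 was lost without NA1363 replicate 4 (-0.19, limma adjusted p = 0.0517), CV125 replicate 1 (-0.21) or CV125 replicate 5 (-0.21). That of ureA was lost without CV125 replicate 5 (-0.55), 6 (-0.52) or 7 (-0.54), and that of flbB without CV125 replicate 5 (0.26) or 6 (0.27) or NA1363 replicate 2 (0.26) or 3 (0.25).

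The strain difference changed with slide order for 60 genes (limma adjusted p under 0.05, a term for strain by slide). Among named genes the change per slide was -1.59 for the alternative oxidase AN2099, -1.18 for hsp20 (AN5781), -0.87 for AN3555, -0.84 for AN7295, -0.67 for hsp104 (AN0858), -0.54 for hsp78 (AN1163), -0.51 for uaZ (AN9470), -0.35 for AN2746, -0.34 for hsp70 (AN5129), 0.45 for the translocon subunit AN0417 and 0.27 for AN4015. The strain difference of AN4015 was no longer called without CV125 replicate 1 (-0.24), 5 (-0.26), 6 (-0.28) or 7 (-0.28) or NA1363 replicate 1 (-0.27) or 2 (-0.28). For a strain difference that changed between the presumed batches limma called 0 genes (420 at an unadjusted p under 0.05).

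Within CV125, 304 genes moved with slide order, with heat shock genes and the alternative oxidase among them. A difference between slides in hybridisation or scanning that shifts both strains alike would move NA1363 too. The median slope of these genes in the CV125 direction was, however, 0.0223 (SE 0.0037) in NA1363. It was 0.249 in CV125, a value that leans high because the genes were chosen by that slope. For 924 genes chosen in presumed batch 1 of CV125, the median was 0.0142 in NA1363 of that batch and 0.132 in CV125 of batch 2. A slide effect that draws ratios towards 0 was not tested by these values. It would move mainly the strain far from 0, as CV125 was for AN2099 (-3.54, against 0.50 in NA1363) and hsp20 (-2.60, against 0.90). AN1549, at -4.6 in CV125, moved little there (slope 0.04 per slide). The SEs in this paragraph are over genes read on the same arrays and do not measure the spread between cultures. An effect of the array's column on its slide is argued against by the order of the arrays. CV125 ran through the columns in opposite order in the presumed batches. Yet 781 of the 924 genes with a slope at an unadjusted p under 0.01 in batch 1 kept their direction in batch 2 (median slope 0.132, SE 0.0065). The Cy5 reference moved by -0.0421 (SE 0.0039) against 0.215 in Cy3, which argues against shifts of single genes in Cy5. These Cy5 values were first brought to one distribution on all arrays. A fall of the whole channel, as seen on slide 4, could therefore not show in them. Growth or harvest of the CV125 cultures stays open and may be behind it: cultures of one number lie on 1 slide, and 0 numbers lie on several, so culture order and slide cannot be told apart. No biological explanation was tested, since the labels give the cultures of CV125 no other difference.

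The genes at least 2-fold higher in NA1363 had smaller strain differences on later slides, with a median of 1.67 on slide 1 and 1.23 on slide 4. The movement seen from slide 1 to slide 4 as the whole reason is argued against by 200 genes chosen on slides 2 and 3, whose median difference was still 1.136 on slide 4 (SD 1.01 over genes, 1.63 on slide 1), with 0 of them turned. It was 1.39 on slide 1 and 1.13 on slide 4 for the 141 that were not among the 304 genes, and 2.71 and 1.25 for the other 59. A displacement of all CV125 cultures that had not ended on slide 4 stays open. Of the 200 genes, 17.5% differed as much on slide 4 as on slide 1, between the bounds of 5 and 25% set for that test. The SE of that share, 2.69, takes the genes as independent, although they share the same arrays. Since culture and strain go together, such a displacement cannot be told apart from a difference of the strains. The strain itself stays among the possible sources, and for AN1549 the difference was 5.53 to 5.75 on each slide.

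The trpC probe was 57.3-fold higher in NA1363. A change of the chromosome region is argued against by the 6 tested neighbours of trpC, whose median difference was 0.09 (0.087215 unrounded, SD 0.26), though 1 of them, AN0644, was called at 0.65. Swapped arrays are argued against by lacZ, which put 0 of 16 arrays with the other strain. That the probe reads a trpC stretch carried by the construct, which per the labels holds the trpC terminator, may explain the value but stays open, since only 1 trpC probe was on the array and none could serve as a control outside that stretch. A higher level of the native trpC transcript cannot be told apart from it.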

How the results depend on the processing

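The fits on slides 1 and 2, on slides 3 and 4, on all slides without genes that moved with slide order, and of the riboflavin list without riboB were chosen after the data had been seen; all other alternatives were planned. Over 35 alternatives for 130 named genes, 4042 of 4420 values kept their direction and their side of the threshold, 345 kept the direction and lost the call, 5 gained one and 28 turned. Unless a reason is given, the cause was not tested. Aquantile changed no ratio (largest change 0), so it tests nothing here. With each array left out, 2257 to 2846 genes were called, 188 to 212 of them at least 2-fold, and 5 to 9 lists. Signal over background limits lacZ in CV125, where 1 probe was above it on 2 of 8 arrays.

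Against 2613 changed genes, the Cy3 channel alone called 3977 (1542 higher, 2435 lower; 38.8% higher against 52.1%). Presumed batches 1 and 2 gave 1684 and 1517, slides 1 to 4 alone gave 601, 456, 150 and 35, and slides 3 and 4 gave 649 against 2114 on slides 1 and 2, a fall with slide order at equal array numbers. The Cy5 signal was also lowest on slide 4, and its CV125 arrays, replicates 4 and 8, had the lowest array weights (0.57 and 0.32). A poorer reading on slide 4 and a movement of CV125 were not separated by these counts. Against 195 genes changed at least 2-fold, the processed signals gave 368 and the deposited log2 ratios 367. Against 6 lists, the 8 arrays whose title and description name the same strain gave 10, and an estimated correlation 1.

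With groups from the description field, which follow the presumed batches instead of the strains, 580 genes were called and the differences were lacZ 0.0091, riboB (AN0670) 0.0384, trpC (AN0648) -0.0582 and pabA (AN6550) -0.0186. Median centring turned gpdA (AN8041) to 0.0153, and on slides 3 and 4 pabA was 0.41 and not called (adjusted p = 0.076). Of the 130 named genes, 69 lost the call there, 60 kept it or stayed uncalled and 1 turned; on slides 1 and 2, 22 lost it. At an unadjusted p under 0.01 the odds ratio of chromosome III turned to 0.993 from 1.01, and that of chromosome IV passed at 1.26 (adjusted p = 0.0458).

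Genes that turned were not called in the alternative. With Cy3 alone these were AN3729 (-0.0939) and AN6317 (-0.0294), and AN3729 on slides 3 and 4 (-0.0042). AN6317 turned also with the brightest probe (-0.0107), in batch 1 (-0.166), on the 8 arrays (-0.0020), with array weights (-0.0246), on slides 1 and 2 (-0.0087) and with arrays left out (-0.0430 to 0.060). AN2623 turned with the brightest probe (-0.0423), on the 8 arrays (-0.194) and with arrays left out (-0.0054 to 0.0911), AN6838 with the brightest probe (0.0385), array weights (0.0078) and arrays left out (-0.050 to 0.0033). The 8 arrays also turned AN7893 (0.541), AN7899 (0.187), AN5893 (-0.0089), AN8540 (0.121), AN0338 (0.171), AN6431 (0.0355) and AN3348 (0.0463); they set presumed batch 1 of CV125 against batch 2 of NA1363.

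A fit with the replicate number as a block (replicate block) called 2855 changed genes (1475 higher, 1380 lower), 197 of them at least 2-fold, and 5 lists, with the riboflavin list no longer called (adjusted p = 0.0684). Same-numbered arrays share a slide and a presumed batch, but the labels name no pairs, so the main fit held no such term. Same-numbered arrays correlated in their deviations at 0.0516 to 0.443, 6 of 8 over 0.1. Only 2 of 8 arrays correlated best with their own number, which decides little, since each slide holds 2 arrays of either strain. The main fit thus leaves out deviations that same-numbered arrays share.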

Other observations

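All tests in this part were chosen after the data had been seen. Sterol synthesis genes formed no list fixed earlier, though AN1901 stood in that of cytochromes P450. They were looked at because a C-4 methylsterol oxidase was among the highest genes. Of 36 measured genes found by words for sterol and mevalonate pathway products, 14 rose in NA1363 and 6 fell (limma adjusted p under 0.05), with a mean log2 difference of 0.39 and a median of 0.14. Behind AN8907 (5.00, SE 0.17) came the sterol C-methyltransferase gene AN1614 at 2.32 (SE 0.14), the sterol 14 alpha-demethylase AN1901 at 1.91 (SE 0.11), the C-4 methyl sterol oxidase AN6973 at 1.32 (SE 0.10), the squalene epoxidase AN11008 at 1.11 (SE 0.07) and the ERG3 desaturase AN6506 at 0.84 (SE 0.13). HMG-CoA reductase (AN3817) fell by 0.88 (SE 0.09), farnesyl-diphosphate farnesyltransferase (AN10396) fell by 0.33 (SE 0.06) and farnesyl-pyrophosphate synthetase (AN8012) fell by 0.25 (SE 0.07), whereas the kinases of mevalonate (AN3869) and phosphomevalonate (AN2311) rose by 0.38 and 0.32, and the late enzymes Cyp51B (AN8283) and 24-dehydrocholesterol reductase (AN8967) were lower, at -0.24 and -0.27. Whether early and late steps differed was not tested. The list also holds genes outside the pathway, such as oxysterol-binding proteins, and 3 of its genes moved with slide order in CV125.

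Whether sterol synthesis shifts as a group in NA1363 is a hypothesis that needs other samples. Camera gave the list p = 0.00197 with the preset correlation and p = 0.0298 with an estimated one, both unadjusted. Without AN8907, which prompted the list, the mean was 0.25 and these p were 0.00835 and 0.0543, so the result with the estimated correlation rested on that gene. The list was written after its leading genes had been seen, so the test leans towards a small p.

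The reference pool gives a hint about the strains that have no arrays of their own. On a scale where the CV125 level is 0 and the NA1363 level is 1, the pool stood at 0.558 for lacZ and 0.596 for trpC, whose construct 3 of the pooled strains carry per the labels. The next values are for 21 genes at least 4-fold higher in NA1363 whose slope by slide order in CV125 did not pass the threshold. Some of them may still have moved, such as pdcA (AN4888) with a slope of 0.40 per slide (limma adjusted p = 0.107). Their median was 0.545, from 0.279 (AN2798) to 0.670. Of the 21 genes, 0 lay under 0.192, a share of 1 in 3 of the mean of lacZ and trpC. This is consistent with these genes being raised in the other transgenic strains as well, a hypothesis that arrays of NA1360 and NA1359 alone would test. The shares of the strains in the pool are not given in the sources used here, a single strain that holds most of the pool would give a like value, and dyes were not swapped.

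For alcR the pool stood at -0.0121 (SE 0.0563), at the CV125 level. Taken at face value, this position would argue against alcR being as low in the other transgenic strains. It also lies below 0.192, the level expected if NA1363 alone among equally pooled transgenic strains had lost the transcript, so that reading is not met either. Without swapped dyes, a dye effect on this single gene cannot be told apart from a difference in the pool. The state of alcR in NA1360 and NA1359 therefore stays open. The alcR level in CV125 also moved with slide order, by 0.17 per slide (limma adjusted p = 0.0361). Of its 6 tested neighbours only alcA (AN8979) was called, at -0.33, which argues against a change of the wider region; a change at alcR itself and lower transcription through a regulator elsewhere were not separated.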
